A study of Mus musculus with 10 samples.

How the data were processed

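RNA from M-1 cells, a mouse cortical collecting duct line, was measured on spotted cDNA microarrays read in both colours. Per the series' design text, cells received 100 nM dexamethasone or steroid-free medium for 3 h, RNA was reverse-transcribed from oligo-dT primers carrying capture sequences, and Cy3 or Cy5 dendrimers were bound to those sequences. Slides were scanned on a ScanArray confocal scanner and spots quantified in Imagene 4.0, per the same text. The values the authors deposited are spot intensities on a linear scale, in whole numbers, 1 column per channel. Background correction, normalisation and any spot filter are not given in the sources used here.

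The 10 channels formed 5 pairs. In 3 pairs, named by array number in the titles, Cy5 held RNA of treated cells and Cy3 held control RNA. In the other 2 pairs both channels were titled control and were joined by the number in their titles. No label says that channels joined in this way share a slide. Checked in the data, the joined channels had the same blank spots (178 of 178 and 258 of 258, against 3 shared by channels of different number), and their log2 intensities correlated across spots at r = 0.933 and 0.927, against 0.727 to 0.782 between numbers. Titles set the groups. The treatment protocol field names dexamethasone for 5 of the 7 channels titled control, so the labels contradict each other, and every direction given here rests on the titles. Nothing in the labels says whether replicates came from separate cultures, so limma p-values measure only the spread between these samples, which may be technical. No dye swap was made. Dye and treatment run together within the treated arrays, and the control pairs lie on other arrays than the treated pairs, so a difference between those sets of arrays and the treatment cannot be told apart.

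The deposited intensity table covers 15600 clones with 2 neighbouring spots each. The control pairs list 31022 and 30942 spots. The treated arrays list 3778, 3994 and 4002, which are 12.1%, 12.8% and 12.8% of the spots. The same spots are listed in both channels of an array, and in each treated array their log2 ratios leave an empty band around the centre whose width depends on intensity. The treated arrays therefore hold spots with outlying ratios alone. The rule that selected them is not stated, and a clone without a value on a treated array had either a ratio inside the band or no usable spot. The number of arrays limits the precision.

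Log2 Cy5/Cy3 ratios were formed per spot with no value added. Control pairs were centred by lowess on intensity (statsmodels 0.14.6, span 0.2). Because loess is biased by the missing middle, each treated array was centred on the midpoint of its empty band, found in windows of 150 spots along intensity and smoothed with a span of 0.3. This replaced the loess planned before the data were examined. Spots of a clone were averaged, and some treated values rest on 1 listed spot of the 2. Treated values hold only spots outside the band and control values hold all, so treated ratios can be too large in size and their SD too small. The planned test was limma 3.58.1 in R 4.3.3 (statmod 1.5.0), comparing the mean of the 3 treated pairs with the mean of the 2 control pairs, with Benjamini-Hochberg adjustment and a threshold of 0.05. It was run on the 213 clones valued in all 5 pairs. A fit on the 8056 clones listed on any treated array was added as an alternative after the data were seen. The 213 clones were selected by the listing for large ratios, so unadjusted p-values of the planned fit run low. The simulations assumed a rule that keeps the largest ratios, and normal noise, as the true rule is not stated, so their rates are approximate. In 5 simulated data sets with no changed clone, truncated by this assumed rule, 31.4% of the clones had an unadjusted p under 0.05 and limma made 0 calls. With 200 changed clones per data set, 236 of 1020 limma calls were false.

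A further test was added after seeing that the treated arrays were truncated. It counts the spots of a clone listed higher minus those listed lower over the treated arrays, from -6 to 6, and takes its p from the exact distribution of that count when arrays are independent, with Benjamini-Hochberg adjustment over all 15600 clones. That p sets a clone against the counts of all clones and holds no spread between samples. A call also required each treated array to lie beyond both control pairs. In the simulations this listing test recovered 10.8% of clones changed by 0.5 on the log2 scale, 85.6% of those changed by 1 and 99.6% of those changed by 1.5. Of 755 calls 15 were false, and 1 call was made over the 5 simulated data sets without a change.

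Gene lists were fixed before the data were examined, 17 in all. Spot counts of a list take all its clones, while gene counts take 1 clone per gene, the brightest on the control pairs. The limma clones held too few list members to test, so camera in limma was run with 1 clone per gene on listing scores, with the control pairs listed in the same manner and the same contrast, which departs from the plan. Camera used a preset correlation of 0.01. In the simulations 4% of 250 random lists had a camera p under 0.05. Those lists drew clones singly and used centred ratios, with missing values set to 0, in place of listing scores. The error rate of camera on listing scores was therefore not measured. For fry, the rotation test, genes with no spread were left out after its first output was seen.

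Genes were named by a rule fixed before the data were examined. It took 13 genes of glucocorticoid response and sodium transport, of which 5 have a clone; up to 12 clones per direction past the limma test; where under 5 passed, the 10 clones per direction with the smallest p, with each treated pair beyond both control pairs and above-median intensity; and up to 4 members of each list with the smallest p. Genes named outside the rule are said to be so. Of the 15600 clones, 9866 carry 1 gene symbol, 274 several and 5460 none, for 7142 genes. Of these clones, 9760 have an identifier found in the mouse gene table of assembly GRCm38.p6, and 0 symbols changed. Clones with several symbols or none are given by clone number. Tables were made in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6, and plots with matplotlib 3.10.9. Alternatives changed the centring, the dye correction, the pairing, the filter on intensity, the test and the arrays used. The fits with the Cy5 channels alone, with no replicate block and with the pair as a random block used log2 channel intensities in place of ratios. These intensities were quantile-normalised over the clones valued in every channel used, which were selected for outlying ratios.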

Results

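Expression was measured in M-1 cells, a cell line from the mouse cortical collecting duct, after 3 h with 100 nM dexamethasone, a synthetic glucocorticoid. Control RNA was hybridised as 5 Cy3 and 2 Cy5 channels and RNA of treated cells as 3 Cy5 channels, giving 3 treated pairs and 2 control pairs. Median spot intensity ran from 327 to 1076 in the channels of the control pairs and from 355 to 880.5 in those of the treated pairs. The treated pairs list 3778, 3994 and 4002 spots of 15600 clones with 2 spots each, those with outlying ratios. A clone without a value there thus has no measured fold. Centred treated ratios start at 0.29, 0.48 and 0.27 in size (log2), while control ratios are not cut. A treated mean set against a control mean can therefore be enlarged by the selection, and its SD narrowed. The treatment field names dexamethasone for 5 of the 7 channels titled control, and the titles were followed.

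The comparison of treated with control pairs asks which transcripts dexamethasone alters early. The Cy5/Cy3 ratio of Ube2g2, a ubiquitin-conjugating enzyme, was lower in the treated pairs. Its clone 11351 had a treated ratio of -2.85 ± 0.41 (SD, log2, n = 3) against 0.27 in the control pairs (n = 2). The limma difference was -3.12 with a standard error of 0.31 and an adjusted p of 0.0282, lower in 3 of 3 treated pairs. Its Cy3 control channels read 859 and 677.5 on the control arrays but 2654, 3379 and 15210 on the treated arrays, while the dexamethasone channels read 507.5, 392 and 1849. Relative to the control arrays its excess was 3.06 in Cy3 and -0.47 in Cy5 (log2), so the lower ratio lies mostly in the control channel, and a fall of the transcript in treated cells was not shown by Cy5 alone. Tekt2, a structural protein of cilia and flagella, had the highest limma difference among the clones named by p, 1.61 with a standard error of 0.29, and did not pass in limma (adjusted p = 0.210). Sgk1, the kinase that raises sodium channel activity in the collecting duct and a known glucocorticoid target, had a ratio of 0.77 ± 0.14 (SD, log2, n = 3) against 0.05 in the control pairs, and did not pass either (limma difference 0.71, standard error 0.21, adjusted p = 0.210). Only 1 of the 2 Sgk1 spots was listed on each treated array. Its difference was 0.33 with median centring and 0.28 with no normalisation, and turned to -0.49 with the Cy5 channels alone. The control Cy3 intensity of Sgk1 stood apart in replicate 1, at 0.22 against a median of -1.47 in the others (scaled log2).

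Of the 213 clones in the planned limma fit, 0 were higher and 1 was lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 22 higher and 26 lower, a share of 22.5%, where simulated data without a change gave 31.4%. The plain t statistic called 0 higher and 0 lower. Without any 1 of the 5 pairs limma called 0 clones, and with all 10 channels fitted separately, or with the pair as a random block, it also called 0. With the Cy5 channels alone it called 0 as well, and the difference was -0.96 for Ube2g2 and 0.45 for Tekt2.

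**Figure D1:**
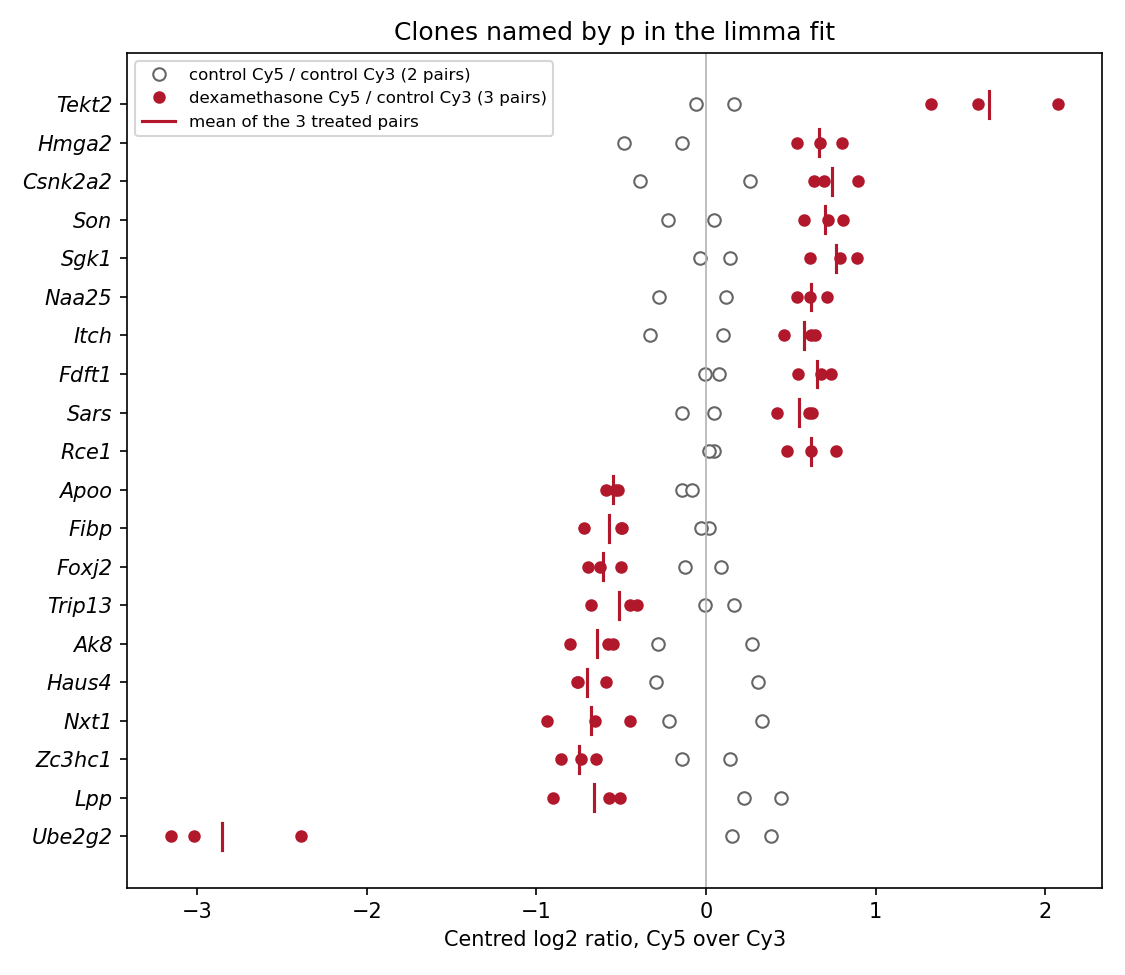
Centred log2 Cy5/Cy3 ratio of the clones named by the smallest limma p, with filled points for the 3 treated pairs, open points for the 2 control pairs and a bar for the mean of the treated pairs. Ube2g2 lies at -2.85 on average and Tekt2 at 1.67, and the others lie between these.

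By p alone, Hmga2, a chromatin protein of growing cells, had a limma difference of 0.98 (standard error 0.22), Son, a splicing cofactor, 0.79 (0.21) and Fdft1, the squalene synthase of sterol synthesis, 0.62 (0.20). Csnk2a2, Naa25, Itch, Sars and Rce1 had differences from 0.59 for Rce1 to 0.81 for Csnk2a2. On the lower side Lpp, a protein of focal adhesions, had -0.99 (0.23), Zc3hc1, a nuclear protein, -0.75 (0.21) and Nxt1, a nuclear export factor, -0.73 (0.28). Foxj2, Fibp, Trip13, Haus4, Ak8 and Apoo had differences from -0.71 for Haus4 to -0.44 for Apoo. None of the clones in this paragraph passed, with limma adjusted p from 0.210 to 0.265. With the Cy5 channels alone Hmga2, Son, Naa25, Sars, Rce1, Nxt1, Foxj2, Fibp, Trip13 and Ak8 had the opposite sign. Without 1 control pair the difference was 0.48 for Csnk2a2 and -0.41 for Haus4 (replicate 1 left out) and -0.46 for Nxt1 and -0.36 for Ak8 (replicate 2 left out), and median centring gave -0.11 for Fibp, -0.30 for Ak8 and -0.63 for Lpp, while scaling the spread gave -0.17 for Apoo. Clones of a gene also differed, with 2 of the 4 Sars clones listed higher and 2 lower, 2 of the 4 Hmga2 clones higher and 1 lower, and 1 of the 4 Csnk2a2 clones higher and 1 lower.

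Counting spots listed one way over the treated arrays, a test added after the data were seen, called 3 clones higher and 3 lower. Tekt2 had 6 of 6 spots listed higher and a treated ratio of 1.67 ± 0.38 (SD, log2, n = 3). Rpsa, a protein of the small ribosomal subunit, was listed higher at clone 4698, with 0.78 ± 0.18 (SD, log2, n = 3) against 0.36 in the control pairs. Part of its ratio was thus seen in the control pairs too, which the p of this test does not subtract. Its Cy5 excess over the control arrays was 0.18 (log2). The clone was chosen after its values were seen, and of the 7 Rpsa clones 4 were listed higher and 1 lower. Zc3hc1 was listed lower, with -0.75 ± 0.10 (SD, log2, n = 3) against 0.00 in the control pairs. Ube2g2 was the other named clone past this test with a lower ratio. Clones 8401 and 11683, also chosen after their values were seen, carry no single symbol and had 1.09 ± 0.12 and -0.69 ± 0.14 (SD, log2, n = 3) against -0.05 and -0.03. Clone 11683 was brighter on the treated than on the control arrays, with an excess of 2.72 in Cy3 and 2.41 in Cy5 (log2). Its dexamethasone channels read 2146, 2956 and 1492 and its control Cy5 channels 259 and 1074, so Cy5 alone showed no fall. For Zc3hc1 the excess was 0.31 in Cy3 and -0.76 in Cy5. Each called clone had an adjusted p of 0.00802 by the exact listing test. Before the requirement on the control pairs 7 clones passed, and the other 9 sets of 3 pairs, each holding a control pair, passed from 0 to 5 clones.

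At a net of 5 or more listed spots there were 15 clones higher and 13 lower, against 0.74 and 0.73 if arrays were independent, but the adjusted p of this step was 0.0523. Simulated data with no changed clone, but with the effect shared by the control pairs, gave a mean of 6.89 such clones in both directions together (3 to 14). Gnai2, an inhibitory G protein subunit chosen after its values were seen, had 6 of 6 spots listed higher and a ratio of 0.73 ± 0.22 (SD, log2, n = 3), but was not called because its treated ratios were not all beyond both control pairs. Without any 1 of the 3 treated arrays the listing test called 0 clones, since fewer spots remain, and median centring left 1 higher.

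**Figure D2:**
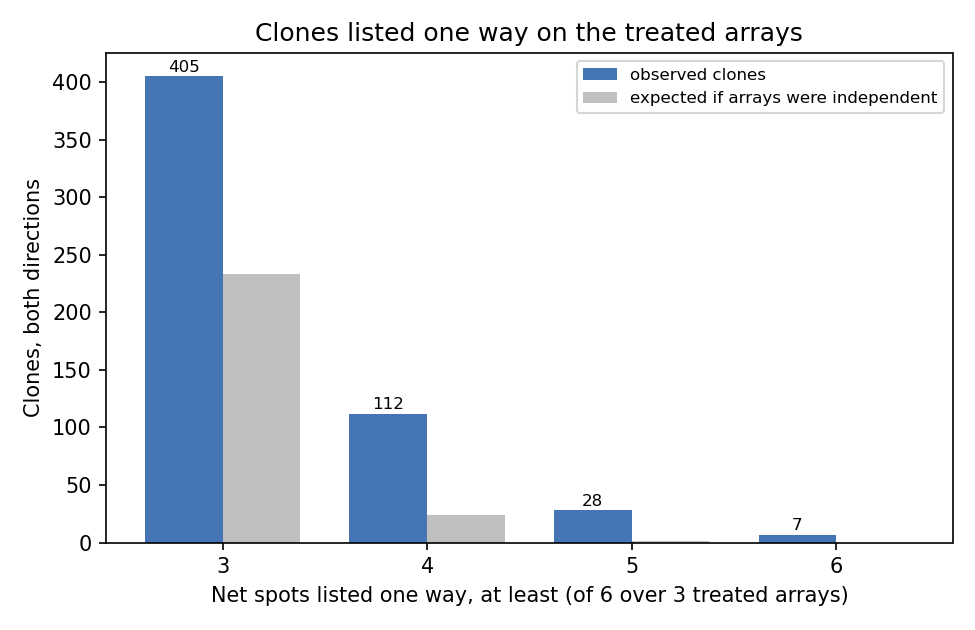
Clones by the net number of spots listed one way over the 3 treated arrays, both directions together, with the observed number in blue and the number for independent arrays in grey. At a net of 5 or more there were 28 clones, and at 6 there were 7. Simulated data with a shared effect and no changed clone, not drawn, gave a mean of 6.89 at a net of 5 or more.

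By size alone, 2 clones were at least 2-fold higher in all 3 treated pairs and under 2-fold in both control pairs, Tekt2 and clone 8401. Ube2g2 was the 1 clone lower by this rule. The other 9 sets of 3 pairs, each holding a control pair, gave 0 higher and 0 lower. The control pairs are not truncated to outlying ratios, and their centred ratios had an SD of 0.33 and 0.36 against 0.62 to 0.77 on the treated arrays. Few of their clones could reach 2-fold, so the sets are not alike and no conclusion is drawn from the 0.

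**Figure D3:**
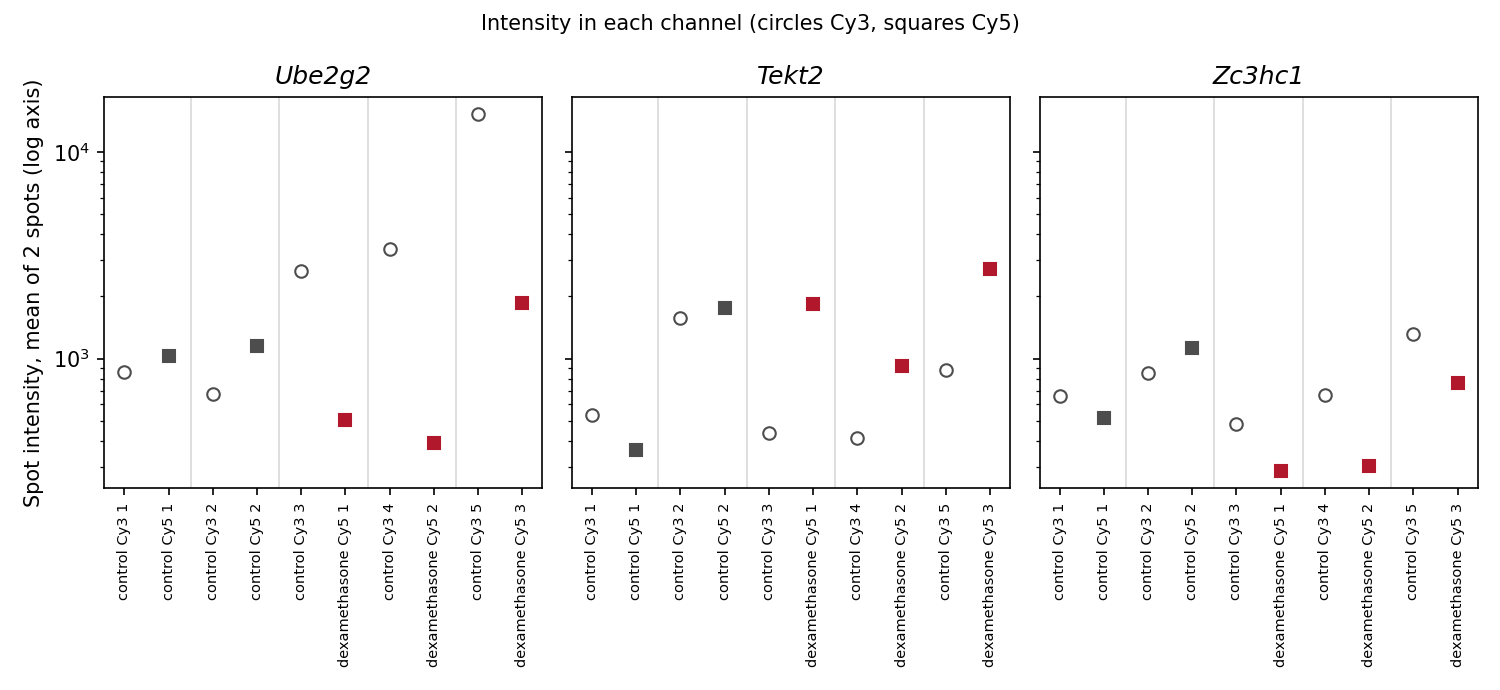
Spot intensity of Ube2g2, Tekt2 and Zc3hc1 in each of the 10 channels on a log axis, mean of 2 spots, with circles for Cy3, squares for Cy5, grey for control and red for dexamethasone, and lines between arrays. The Cy3 control channel of Ube2g2 reads 15210 on the last array and 677.5 on the 2nd control array.

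Among the genes fixed by name, Nfkbia, the inhibitor of NF-kB and a glucocorticoid target, was listed in 2 treated arrays, at 1 spot each. Its ratio was 0.71 ± 0.21 (SD, log2, n = 2) against -0.30 in the control pairs. Atp1b1, the beta subunit of the sodium pump, was listed once for each of 3 clones, at 0.45, 0.49 and -0.72 on the log2 scale, with control pairs at -0.22, -0.54 and -0.21. Fkbp5, a co-chaperone of the glucocorticoid receptor, and Nr3c1, the receptor itself, were listed in 0 treated arrays. Of the 13 fixed genes, 8 have no named clone here.

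Glucocorticoid-induced genes (23 measured) had 19 spots listed higher and 7 lower over the treated arrays, counting all clones. By 1 clone per gene, 9 genes were more often higher and 4 more often lower. By array the spot counts were 7 higher and 1 lower, 2 higher and 3 lower, and 10 higher and 3 lower. Besides Sgk1 and Nfkbia these held Gadd45g, a stress-response protein, with 0.71 ± 0.11 (SD, log2, n = 2) against 0.29 in the control pairs, and Klf9, a transcription factor, with 0.60 in 1 array against -0.14. In the sodium transport list (16 measured), 15 spots were higher and 4 lower, with Slc12a2, a sodium, potassium and chloride cotransporter, at 0.69 ± 0.12, Slc4a1, the anion exchanger of intercalated cells, at 0.81 ± 0.17 and Ywhab, a 14-3-3 protein, at 0.64 ± 0.17 (SD, log2, n = 2 each). Their control pairs averaged -0.16, 0.05 and -0.09. The treated means of these genes rest on 1 listed spot per array. Of the 3 Slc12a2 clones 2 were listed higher and 1 lower. With the control pairs listed in the same manner, 1 had 7 sodium transport spots higher and 0 lower and the other had 1 higher and 4 lower. Glucocorticoid-repressed inflammatory and immediate-early genes (15 measured) had 9 spots higher and 8 lower, counting all clones. By 1 clone per gene, 4 genes were more often higher and 7 more often lower. The chemokines Cxcl1 and Cxcl12 stood at 0.76 ± 0.05 against 0.53 in the control pairs and at 0.78 ± 0.27 against 0.09 (SD, log2, n = 2 each). Myc, a growth regulator, stood at -0.53 ± 0.08 against 0.12 (SD, log2, n = 2). Cxcl12 and Myc had 1 listed spot per array.

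Chaperones (26 genes measured) had 50 spots listed higher and 8 lower, counting all 69 clones. By 1 clone per gene, 9 genes were more often higher and 0 more often lower. Hspa5, the chaperone of the endoplasmic reticulum, stood at 0.97 ± 0.50 against 0.30 in the control pairs and Fkbp4, a co-chaperone of steroid receptors, at 0.80 ± 0.04 against -0.23 (SD, log2, n = 2 each). The Fkbp4 values rest on 1 listed spot per array, and of the 3 Fkbp4 clones 2 were listed higher and 1 lower. The control pairs, listed in the same manner, had 30 chaperone spots higher and 14 lower. Cell cycle genes (37 measured) had 35 spots higher and 12 lower, with Ube2c, a ubiquitin-conjugating enzyme of mitosis, at 0.74 ± 0.07 against -0.01 in the control pairs and Tuba1b, a tubulin, at 0.62 ± 0.18 against 0.33 (SD, log2, n = 2 each). Sterol and lipid synthesis genes (12 measured) had 14 spots higher and 3 lower. Lss, the lanosterol synthase, stood at 0.85 ± 0.08 (SD, log2, n = 2) against 0.29, with 1 listed spot per array. Cytoskeleton and junction genes (36 measured) had 48 higher and 18 lower, 29 of the higher spots on the first treated array.

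None of the 17 lists passed camera in limma in any setting run, and none of the 16 lists fry could test passed it. With the preset correlation and all pairs, the smallest adjusted p by limma's camera was 0.577, shared by the sodium transport, fibroblast and proteasome lists. At an unadjusted p under 0.05 there were 0 lists in this setting, but the glucocorticoid-induced list was under it with median centring, ribosomal proteins with fry, sodium transport without treated replicate 2 or 3, the proteasome without treated replicate 2, and sodium transport, chaperones and sterol synthesis when treated pairs were tested against 0. Over the other camera settings the smallest adjusted p was 0.180, with treated pairs tested against 0. With an estimated correlation the smallest adjusted p was 0.796, and with fry it was 0.217. Adjusted over the list alone, the listing test passed 1 inflammatory gene, 2 cell cycle genes and 1 sterol gene, all higher, and 0 genes of the other lists, with 1 clone per gene and without the requirement on the control pairs. Cxcl1 was the inflammatory gene, Ube2c and Tuba1b the cell cycle genes and Fdft1 the sterol gene. Their treated means exceeded those of the control pairs by 0.24, 0.75, 0.29 and 0.62. The p of the listing test takes arrays as independent. Simulated data with a shared effect gave more clones listed one way than independence does, so these p-values run low. Rpsa counts among the 0 because clone 228, not the called clone 4698, stood for the gene.

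Markers of other cell types were listed as follows, which reflects outlying ratios and not expression. Fibroblast and matrix markers (16 measured) had 6 spots higher and 8 lower, leukocyte and endothelial markers (5 measured) 0 higher and 2 lower, and proximal tubule markers (3 measured) 3 higher and 1 lower. Collecting duct markers (14 measured) had 10 spots higher and 5 lower.

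The control pairs, joined by title number, show what the ratio gives when both channels are titled control. Among the 213 clones, limma found 0 with a dye effect, 9 at an unadjusted p under 0.05, and a smallest adjusted p of 0.940. Over all 15561 clones of the control pairs, a wider test chosen after the data were seen, 5 clones were higher in Cy5 and 45 lower, and with median centring 0. Across clones, which are not independent replicates, the centred ratios of the 2 control pairs correlated at r = 0.149, those of a control and a treated pair at 0.0627 to 0.203, and those of the treated pairs at 0.201 to 0.308. The treated values are truncated to outlying ratios and the control values are not, so these r values are not alike. With the control pairs listed in the same manner, clones listed in both pairs had the same direction in 64.8% for the 2 control pairs and in 62.5% to 67.6% for the treated pairs. Between a control and a treated pair the share was 56.2%, 57.7% and 62% for control pair 1, and 56.1%, 55.2% and 66.2% for control pair 2.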

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

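The test for outlying channels was fixed beforehand, and the choice of clones it ran on followed from the limma p-values. Sgk1 stood apart in the control Cy3 channel of replicate 1, at 0.22 on the scaled log2 intensity scale against a median of -1.47 in the other control Cy3 channels. The gap to the nearest channel was 0.741 of the range of the 5 channels. Among 20 clones tested, 1 stood apart in this way, and chance gives about 1 in 20, so no explanation was weighed.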

How the results depend on the processing

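The alternatives for the listing test, limma on clones listed on any treated array, and the dye test over all clones were chosen after the data were seen; the others were planned. The planned limma counts of 0 higher and 1 lower became 50 higher and 52 lower when treated pairs were tested against 0, where simulated data without a change gave a mean of 117.6 calls, so these are not read as changes. The lower count was 0 without the pairing of channels (no replicate block), 0 with the pair as a random replicate block, 0 with the Cy5 channels alone, 0 by the plain t statistic, and from 0 to 0 with each pair left out (smallest adjusted p 0.0627 to 0.303). It was 1 with median centring, no normalisation, scaled spread, 50 added, either intensity filter, array weights, an intensity trend, a threshold of 0.1, and clones listed on any treated array (8056 clones). The cause was not tested.

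The listing test's 3 higher and 3 lower became 10 and 9 at a threshold of 0.1, 10 and 9 without the lowest 25% by intensity, 10 and 8 without the lower 50% by intensity (fewer clones tested), and 1 and 2 with median centring. With each pair left out the higher count ran from 0 to 4 and the lower from 0 to 3. Clones past 2-fold, 2 higher and 1 lower, became 15 and 14 at 1.5-fold and 1 and 1 with median centring. The dye effect's 0 became 50 over all clones. No gene list passed in any alternative.

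Of 395 alternative log2 differences of named genes, 342 kept their direction and side of the threshold, 9 (all Ube2g2) no longer passed (-2.97 to -3.35 with each pair left out, -3.12 by plain t, -2.25 with the pair as a random replicate block, -0.96 with Cy5 alone and -0.92 with no replicate block), 19 passed only against 0, and 25 reversed. With no replicate block the reversed values were Sgk1 -0.48, Hmga2 -1.31, Naa25 -0.26, Rce1 -0.33, Sars -1.38, Son -0.24, Ak8 1.09, Fibp 2.88, Foxj2 0.60, Nxt1 0.84 and Trip13 1.53. With Cy5 alone they were Sgk1 -0.49, Hmga2 -1.36, Naa25 -0.25, Rce1 -0.32, Sars -1.47, Son -0.23, Ak8 1.16, Fibp 2.91, Foxj2 0.64, Nxt1 0.84 and Trip13 1.60. With the pair as a random replicate block they were Ak8 0.009, Fibp 0.65 and Trip13 0.0283. These fits lose part or all of the ratio within an array, and the differences in brightness between arrays enter them. All alternatives listed before the data were examined could be run. Background was not given, so signal over background could not be assessed.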

Other observations

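Every test of an explanation given here was chosen only after the result was seen, while the gene lists were fixed before the data were examined. Oxidative phosphorylation genes (62 measured) had 32 spots listed higher and 19 lower over the treated arrays, where the control pairs also leaned higher, with 9 higher and 6 lower and 15 higher and 5 lower. Ndufaf3, an assembly factor of complex I, stood at 0.73 ± 0.20 against 0.27 in the control pairs and Uqcr11, a subunit of complex III, at -0.64 ± 0.31 against -0.26 (SD, log2, n = 2 each). Ribosomal protein genes (73 measured) had 54 spots higher and 43 lower, where the control pairs had 31 higher and 7 lower and 29 higher and 14 lower, and Rps13 stood at -0.52 ± 0.02 (SD, log2, n = 2) against 0.43. By fry in limma the 30 of these genes left after removing those with no spread leaned lower, with an adjusted p of 0.217. Proteasome genes (30 measured) had 12 higher and 10 lower. Psmd7, a lid subunit, stood at 0.75 ± 0.02 against 0.14 and Psmb5, a catalytic subunit, at -0.36 ± 0.03 against -0.07 (SD, log2, n = 2 each). The treated Psmb5 ratios of -0.34 and -0.38 lie near the edge of the empty band and rest on 1 listed spot each. Psmd7 and Psmb5 each have 2 clones, 1 listed higher and 1 lower. None of these lists passed camera in limma.

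Stress response genes (13 measured) had 11 spots higher and 3 lower, with Slc3a2, a chain of amino acid transporters, at 0.83 in 1 array against 0.12 in the control pairs and Atf3, a transcription factor of stressed cells, at -0.78 in 1 array against -0.08. Circadian clock genes (8 measured) had 3 spots higher and 2 lower, with Npas2 at 0.65 against 0.09 and Cry1 at -0.83 against -0.35, in 1 array each. Histones (2 measured) had 1 spot higher and 1 lower. These lists did not pass camera either. The mean score and camera's direction differed in sign for the cytoskeleton list (mean 0.01, direction lower) and the proximal tubule list (mean 0.00 or just below, direction higher).

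Clones listed the same way on all 3 treated arrays numbered 109, 53 higher and 56 lower, against 21.5 and 19.9 by shuffling (permutation p = 0.001 each, the smallest 1000 shuffles can give). Shuffling within runs of consecutive clones left a ratio of 2.29, which argues against slide position as the whole source. Simulated arrays with no changed clone, but with the ratio shared between the control pairs, gave 118 such clones, and sets of 3 pairs holding a control pair gave from 73 to 115, so a dye or spot effect may account for the number. At a net of 5 or 6 spots there were 28 clones, and 0 of 100 simulated data sets reached that (highest 14). The simulated noise and shared effect were normal, with spreads from the control pairs alone, so heavier tails could give more. These 28 clones had a median control ratio of 0.13 in the direction of their listing against 0.68 on the treated arrays. A shared effect stays open for them. The treated set was the 1 of 10 sets of 3 pairs with as many, the highest other had 17, and 10 sets are too few for a share under 0.05.

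Chaperone spots were listed higher in 86.2% of listings on the treated arrays, and 0.1% of intensity-matched random lists had as large a share (median 59.7%). The random lists drew clones singly, while the 69 chaperone clones come from 26 genes, and clones of 1 gene can move together. The random lists therefore vary too little, for the control pairs as well, and do not settle whether intensity bias has a part. In the control pairs the share was 68.2%, at percentile 96.8 of the random lists, but the pairs differed, with 13 higher and 11 lower in 1 and 17 higher and 3 lower in the other. A dye effect at these clones may account for part of the share, though the evidence for it rests mostly on 1 control pair. An effect of dexamethasone stays open and was not separable from it, as no dye swap was made.

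Clones with a net of 4 or more spots listed lower (60) were brighter on the treated arrays than on the control arrays in both channels, with a median excess of 1.79 in Cy3 and 1.42 in Cy5 on the log2 scale (95th percentile of random sets for Cy5, 0.16). Clones listed higher (52) had 0.13 and 0.43. A difference between the sets of arrays may account for the brightness, which treatment of the Cy5 sample alone would not give in Cy3. At Ube2g2 the control Cy3 channels that the titles and the treatment field both call control differed 5.37-fold after scaling, but 1 lies on a control array and 1 on a treated array, so exchanged labels cannot be told apart there from the difference between arrays. Ube2g2 itself had an excess of 3.06 in Cy3 but -0.47 in Cy5, so it does not show the brightness in both channels, and what raised its Cy3 signal stays open.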
